A study of Mus musculus with 51 samples.

How the data were processed

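Omni-ATAC-seq peak lists of 51 libraries from sorted mouse mammary cells were compared. Groups were taken from the titles and the genotype, treatment and cell type labels. All samples share 1 source name, which speaks of mature luminal cells, and an extraction protocol that speaks of RNA, so the cell type rests on the title and the cell type label alone.

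Peaks were called with MACS2 against GRCm38, per the submitters' processing notes; the version, the aligner and the filters are not given in the sources used here. Each deposited list holds the peaks of 1 library. Per the file layout, the authors' deposited values are a fold enrichment at the summit, which is a ratio, and the -log10 p-value and -log10 q-value of each peak. These scores are the authors' and were used only to rank or filter peaks within a list. Between 17.7% and 31.6% of the entries of a list shared an interval with another summit. The lowest -log10 p in a list was 2.00 at the median and 4.35 in the list where it was highest. Read counts were not analysed here, so depth is unknown and no counting interval can be given.

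Entries with the same interval were collapsed, which left 127464 to 235743 intervals per library. The 50000 with the smallest p were kept, so that every library gave the same number whatever its depth; the -log10 p of the last one kept ranged from 10.1 to 94.8. Windows of 501 bp around summits were chosen greedily by rank on the autosomes and chromosome X, and kept when open in 2 or more libraries of a group. A window was open when a kept interval overlapped it by 100 bp or more. Of 106747 windows, 57.2% lay in a gene body. Gene coordinates came from the GRCm38.p6 RefSeq table, with 21631 protein-coding genes. The table holds no strand, so a window was assigned to the nearest gene body within 100 kb, in place of the nearest transcription start that had been planned, and 99682 windows had a gene. The planned search for sequence motifs was not run because no genome sequence was used here.

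Genes with 2 or more open windows in 3 or more libraries were tested, 13993 in all, on log2(windows + 1), where 1 is the pseudocount, so a log2 difference understates the change of genes with few windows. One limma model with a coefficient per group, no covariates and 34 residual degrees of freedom was fitted to all 51 libraries, with a trended, robust moderation of the spread. Adjusted p-values are Benjamini-Hochberg over the genes of a comparison, and the threshold was 0.05. The spread is that between libraries of a labelled group, so a group that mixes unlike libraries raises it. The 22 gene lists, with 309 genes of which 308 were in the gene table, were tested with limma camera at a preset correlation of 0.01 and again with an estimated one. Similarity of libraries was tested with 100000 permutations of the labels. Of the called genes, those named follow a rule by size of change that covered all of them; 1 is counted but not reported here. In addition, 10 genes, from Esr1 to Kit, are given whether called or not. The tests, the lists, the naming rule and the alternatives were fixed before the data were examined, except where the text says otherwise.

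The gene test was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold among 13993. The changed genes were drawn from those with a mean of 2 or more windows, so recovery is not known for genes with fewer. With binomial draws, it recovered 37% and 87% of them, with 11 unchanged genes called, for giredestrant against vehicle in WT ML libraries, and 62% and 97%, with 5, for N against ML. With real libraries under shuffled labels it recovered 65% and 92%, with 85 unchanged genes called, in the first case, and 65% and 95%, with 0, in the second. In the first case the share of unchanged genes among the calls was above the threshold in both draws. Each setting was drawn once, and shuffled real libraries can differ in profile, so the share over repeated draws is not known. No library was a copy of another: the highest Jaccard index between libraries was 0.877. The library numbers in the file names form 2 runs, of 39 and 12 libraries, which were used as a covariate in an alternative. Other alternatives changed the number of intervals, the overlap, the gene assignment and the filter on genes, added the number of intervals or the replicate number to the model, and left out each library in turn. No library was regrouped or left out for its profile. Versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.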

Results

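Chromatin accessibility was profiled by Omni-ATAC-seq, in which a transposase inserts adapters into open DNA, in cells sorted from mouse mammary glands. The mice carried wild-type Esr1 (WT), the gene of estrogen receptor alpha, or the Y541S or D542G substitution in its ligand-binding domain. All received estradiol and progesterone pellets and were then dosed daily with vehicle or with giredestrant, an oral antagonist and degrader of the receptor, at 30 mg/kg for 4 days. The labels name mature luminal (ML), luminal progenitor (LP) and basal cells, and a population labelled N that the series title describes as emerging in Esr1 mutants under the antagonist. The 51 libraries form 17 groups of 3. ML and Basal libraries, 18 of each, come from all 3 genotypes under both treatments. The 9 LP libraries come from all genotypes under giredestrant, and the 6 N libraries from the mutants under giredestrant. The series text calls the 3 libraries of a group biological replicates.

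Each library was deposited as a list of peaks, with 173632 to 299781 entries and a median of 229842. Read totals were not analysed here, so the sequencing depth is unknown. With the same number of intervals taken from each library, 54324 to 65495 of 106747 consensus windows were open per library, and 19986 were open in all 51. The value compared is the number of open windows assigned to a gene.

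Marker genes did not separate the labelled populations. Krt5, a keratin of basal cells, had 3.22 ± 2.71 open windows in libraries labelled ML (SD, n = 18) and 2.89 ± 2.87 in those labelled Basal (SD, n = 18), and ranged from 0 to 7 within each. Trp63, the basal transcription factor p63, had 8.50 ± 2.66 and 7.83 ± 3.24 in the same libraries. Elf5, a regulator of the secretory luminal lineage, had 3.78 ± 2.24 and 3.94 ± 2.48. Its value in libraries labelled LP was 5 ± 2.45 (SD, n = 9). Kit, a receptor of luminal progenitors, had 7.56 ± 4.19 windows in libraries labelled LP, 5.61 ± 3.50 in those labelled ML and 5.50 ± 3.40 in those labelled Basal. The LP and N libraries are all under giredestrant, and the N libraries all from mutants, while those labelled ML and Basal hold both treatments. In mutants under giredestrant, Kit had 6.67 ± 3.01 windows in libraries labelled LP, 3.83 ± 2.86 in ML and 5.17 ± 3.37 in Basal (SD, n = 6 each). Over the 20 genes of the basal list, the mean number of windows per gene was 5.08 ± 1.57 in libraries labelled ML, 4.69 ± 1.81 in LP, 4.79 ± 1.66 in Basal and 4.92 ± 1.76 in N (SD, n = 18, 9, 18 and 6).

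The spread lay within the labelled groups. The basal list ran from 2.70 to 7.25 windows per gene over the 51 libraries. It reached 6 or more in 18 libraries, of which 7 were labelled ML, 3 LP, 6 Basal and 2 N, and lay under 4.8 in 31, bounds that were set after the values were seen. In WT mice under vehicle, a library labelled ML had 7.05 windows per basal gene and a library labelled Basal had 3.40. Because the marker values go against the labels, every group is given below as the libraries labelled with its name, and a direction is that of the labels.

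**Figure D1:**
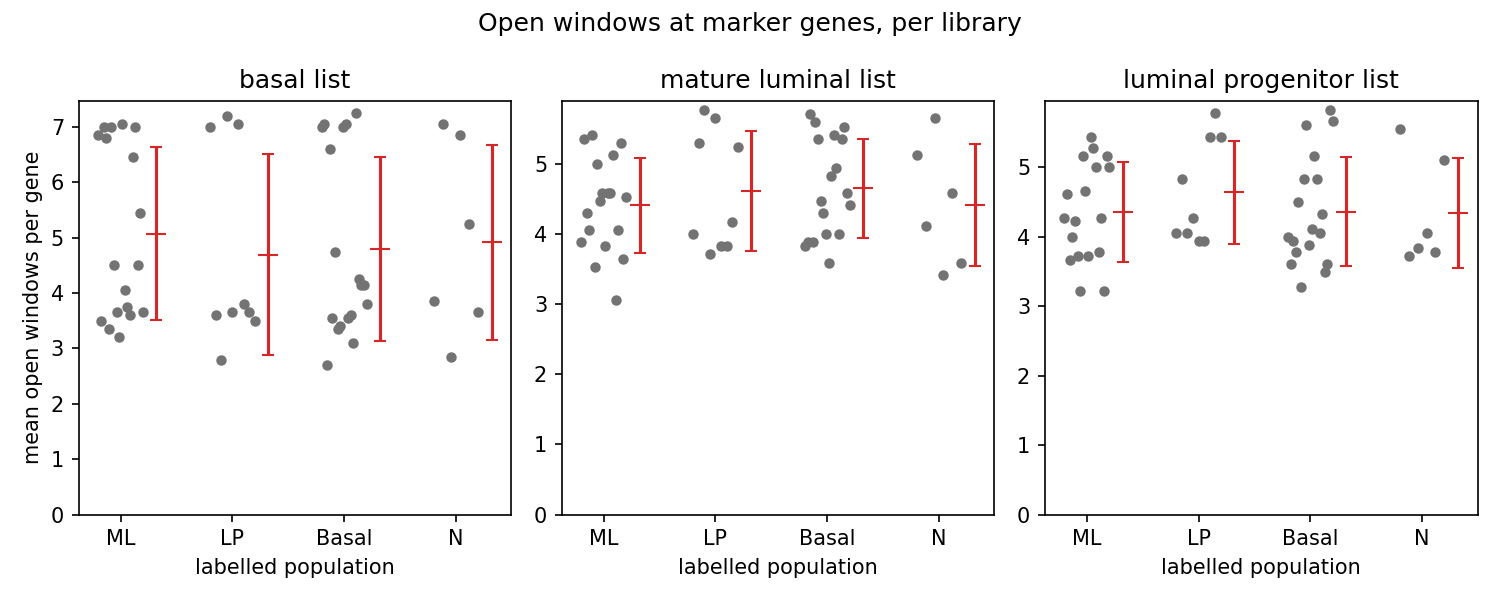
Mean number of open windows per gene (vertical axis) for the basal, mature luminal and luminal progenitor lists, by labelled population (horizontal axis). Each grey point is a library (18 ML, 9 LP, 18 Basal and 6 N), and the red mark and bar are the mean and SD. The basal list spans from 3.20 to 7.05 in libraries labelled ML and from 2.70 to 7.25 in those labelled Basal.

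Libraries labelled ML and Basal were compared over all genotypes and treatments. No gene differed between them among 13993 tested (limma, Benjamini-Hochberg adjusted), and 207 had an unadjusted p under 0.05. Krt14, the partner keratin of Krt5, had 4.61 ± 2.35 windows in libraries labelled ML and 4.22 ± 2.32 in those labelled Basal (SD, n = 18 each). Prlr, the prolactin receptor, had 4.61 ± 3.74 and 5.61 ± 3.71, and Foxa1, a cofactor of the estrogen receptor, 0.72 ± 0.89 and 0.83 ± 0.92. Esr1 itself had 9 ± 1.65 and 9.44 ± 1.65, and Pgr, the progesterone receptor, 4.11 ± 1.23 and 4.11 ± 1.71. Of the 22 gene lists, the basal list passed the test, and it was higher in the libraries labelled ML, with a median log2 difference of 0.10 (limma camera, adjusted p = 0.0436). None of its 19 tested genes passed on its own, also when adjusted over the list alone, and the list had an adjusted p = 0.928 with an estimated correlation. No window was open in all 18 libraries of either label and closed in all 18 of the other.

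The labelled LP libraries were set against the ML libraries under giredestrant, 9 against 9. No gene passed (limma, 236 of 13993 at an unadjusted p under 0.05). The basal list was lower in the libraries labelled LP, with a median log2 difference of -0.16 over 19 genes (limma camera, adjusted p = 0.0123). With an estimated correlation it had an adjusted p = 0.887, and none of its genes passed when adjusted over the list alone. The luminal progenitor list had 4.64 ± 0.74 windows per gene in these libraries labelled LP and 4.21 ± 0.64 in those labelled ML (SD, n = 9 each).

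The population labelled N was compared with libraries labelled ML, LP and Basal of the same mutants under giredestrant. As the markers go against the labels, this describes the labels and not what sets the population apart from known ones. Greb1, a target of the estrogen receptor, had 8 ± 2.83 windows in libraries labelled N (SD, n = 6), 8.17 ± 1.17 in those labelled ML, 7.83 ± 2.40 in LP and 7.67 ± 2.34 in Basal (SD, n = 6 each, mutants under giredestrant). Esr1 had 9.17 ± 2.04 windows in N, Pgr 5 ± 1.26 and Prlr 4.33 ± 3.39. The basal genes Krt5, Krt14 and Trp63 had 2.67 ± 3.08, 4.67 ± 2.58 and 8 ± 2.97. Elf5 had 4.17 ± 2.79 windows, Kit 5.50 ± 3.45 and Foxa1 0.83 ± 0.98. None of these genes passed the test in any of the 3 comparisons. Limma called 0 of 13993 genes against ML, LP and Basal alike, with 203, 201 and 195 genes at an unadjusted p under 0.05 where chance gives 700. None of the 22 lists passed in these comparisons. A single window was open in all 6 libraries labelled ML and in none labelled N, and a single one likewise for Basal.

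The overlap of open windows was taken between the N libraries and each other population. In Y541S mice, the mean Jaccard index, the share of windows open in either library that are open in both, was 0.627 ± 0.181 with ML, 0.652 ± 0.174 with LP and 0.620 ± 0.192 with Basal (SD over 9 pairs). In D542G mice the values were 0.612 ± 0.110, 0.607 ± 0.111 and 0.609 ± 0.0983. The index among the N libraries themselves was 0.555 in Y541S and 0.586 in D542G. Exact two-sided permutation tests between the populations gave p from 0.5 to 1, in a design whose smallest possible p is 0.1. Over all 51 libraries, the mean index was 0.594 within a labelled population and 0.606 between populations (permutation test, p = 0.0914, adjusted p = 0.137 over 6 ways of pairing libraries).

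Between the N libraries of both mutants, Castor1, an arginine sensor upstream of mTORC1 (chromosome 11, 4218166 to 4222409, GRCm38), had 2 open windows in each Y541S library and 1 in each D542G library. It was the only gene that passed (log2 difference 0.58 ± 0.10 SE, limma adjusted p = 0.0183, n = 3 each). Its window inside the gene, from 4218395 to 4218895, was open in 46 of the 51 libraries. The basal list was lower in Y541S, with a median log2 difference of -0.19 (limma camera, adjusted p = 0.0440, and adjusted p = 0.950 with an estimated correlation). The inflammatory NF-kB list was lower too, with a median of -0.16 (adjusted p = 0.0440, and adjusted p = 0.156 with an estimated correlation). None of the 19 and 14 tested genes passed on its own. The mature luminal list had 4.96 ± 0.78 windows per gene in Y541S and 3.86 ± 0.63 in D542G, and the pan-luminal list 7.52 ± 1.38 and 6.74 ± 0.62 (SD, n = 3 each). The basal list had 3.85, 7.05 and 2.85 windows per gene in the Y541S libraries and 6.85, 5.25 and 3.65 in the D542G libraries, so the difference may reflect unlike libraries in each group. Castor1 kept its call in 6 alternatives, omissions of a library included, and lost it in 9.

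Giredestrant was compared with vehicle in libraries labelled ML, a design meant for the response of hormone-sensing cells. Of the 18 libraries labelled ML, 7 had 6 or more windows per basal gene, so the values describe the label and not those cells. In WT mice, Greb1 had 6.67 ± 0.58 windows under giredestrant and 5.67 ± 0.58 under vehicle, and Pgr 4.33 ± 1.15 and 3 ± 0 (SD, n = 3 each). In D542G mice, Greb1 had 8.67 ± 0.58 and 3.67 ± 1.15 and Kit 4 ± 3.46 and 9.33 ± 2.31. In Y541S mice, Greb1 had 7.67 ± 1.53 and 9 ± 0 and Esr1 10 ± 0 and 9.33 ± 3.06. None of these differences passed the test. Limma called 0 genes in WT (785 at an unadjusted p under 0.05), 4 in D542G (1451) and 0 in Y541S (727). In Y541S mice all giredestrant libraries lie in the run of 39 library numbers and all vehicle libraries in that of 12. Treatment and run cannot be told apart there. In WT mice the vehicle libraries lie in the run of 39, and giredestrant replicates 1 and 2 in that of 12.

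The 4 genes called in D542G mice had fewer windows under giredestrant. Fdxr, the ferredoxin reductase of mitochondria, and Ttc16 had 2 windows in each library under giredestrant and 3 in each under vehicle (log2 difference -0.42 ± 0.06 SE, adjusted p = 0.000348 for both, n = 3 each). Tex9 had 1 and 2 windows (log2 difference -0.58 ± 0.09 SE, adjusted p = 0.000653). Mrpl12, a mitochondrial ribosomal protein, had 1 and 2 (log2 difference -0.58 ± 0.11 SE, adjusted p = 0.0211). Each call rests on a single window that was open in 7 or 8 of the 51 libraries. Such a rare window was kept only if 2 or more of these libraries shared a labelled group, which can favour this pattern. Over the alternatives, omissions of a library included, Fdxr kept its call in 10 and lost it in 5, Ttc16 in 11 and 4, Tex9 in 11 and 3, and Mrpl12 in 5 and 9. The luminal progenitor list was lower under giredestrant in D542G mice, with a median log2 difference of -0.52 over 17 genes. It had a limma camera adjusted p = 0.0393, and an adjusted p = 0.680 with an estimated correlation. In the same libraries the basal list had 4.95 ± 1.87 windows per gene under giredestrant and 3.80 ± 0.23 under vehicle, and the pan-luminal list 7 ± 1.13 and 8.10 ± 0.29 (SD, n = 3 each). One giredestrant library had 7 windows per basal gene, so the change may reflect unlike libraries in the group. Windows open in all 3 libraries of a treatment and in none of the other numbered 473 for giredestrant and 548 for vehicle in WT, 669 and 2198 in D542G, and 306 and 138 in Y541S. Other splits of the same 6 libraries gave up to 10019, 3098 and 4402, with medians of 247, 718 and 335. Of 10 splits, the real one included, 3, 2 and 5 gave at least as many windows as the real one.

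The mutants were compared with WT in libraries labelled ML under each treatment. Under vehicle, Ttc16 had 3 windows in each D542G library and 2 in each WT library (log2 difference 0.42 ± 0.06 SE, limma adjusted p = 0.000697, n = 3 each). Mrpl12 had 2 and 1 (log2 difference 0.58 ± 0.11 SE, adjusted p = 0.0421). These were the 2 genes called for D542G under vehicle. Ttc16 kept this call in 11 alternatives and lost it in 4, and Mrpl12 in 6 and 8. Both genes were also called for giredestrant in D542G mice, on the same D542G vehicle libraries and the same single window. The 2 comparisons share that group, so they are not independent and do not show a gain that giredestrant reverses. For Y541S under vehicle no gene passed, with 1403 at an unadjusted p under 0.05. The basal list was higher in Y541S, with a median log2 difference of 0.41 over 19 genes (limma camera, adjusted p = 0.0287, and adjusted p = 0.946 with an estimated correlation). The pan-luminal list was lower, with a median of -0.24 over 14 genes (adjusted p = 0.0287, and adjusted p = 0.946 with an estimated correlation), and 1 of its genes passed when adjusted over the list alone. Krt5 had 5.67 ± 2.31 windows in Y541S and 2.33 ± 3.21 in WT. The basal list had 6.45, 7 and 4.50 windows per gene in the Y541S libraries and 3.65, 3.20 and 7.05 in the WT libraries. These differences may therefore reflect unlike libraries in each group. Under giredestrant, limma called 0 genes for Y541S (439 at an unadjusted p under 0.05) and 0 for D542G (792). All Y541S vehicle libraries belong to a run of library numbers that holds no WT vehicle library, so no value within the run can be given. With the run as a covariate, limma called 1010 genes for Y541S under vehicle. Only WT giredestrant libraries lie in both runs, so the covariate is estimated from their replicate 3 against replicates 1 and 2. Replicate 3 had 6.8, 7.2 and 6.6 windows per basal gene in libraries labelled ML, LP and Basal, and the others had 3.5 to 5.45. The 1010 calls may carry this difference and are not an effect freed of the run.

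Whether giredestrant acted differently on mutant and WT ML libraries was tested as an interaction. For Y541S, limma called 6 genes. Ucp2, a mitochondrial carrier (chromosome 7, 100493337 to 100499629, GRCm38), had 2 windows in each Y541S giredestrant and WT vehicle library and 1 in each Y541S vehicle and WT giredestrant library (log2 interaction 1.17 ± 0.17 SE, adjusted p = 0.000741, n = 3 per group). Fgf12, a fibroblast growth factor homologue, had 0 windows in every Y541S giredestrant library and 3 ± 1 under vehicle, against 2.33 ± 0.58 and 1 ± 1.73 in WT (log2 interaction -3.03 ± 0.60 SE, adjusted p = 0.0477). Zbtb4 and Ifi27l2b had positive interactions of 2.72 and 1.86. Parg, which degrades poly(ADP-ribose), had a negative interaction of -1.21, and these 3 genes had a limma adjusted p = 0.0477. Both windows of Ifi27l2b lie outside the gene, 35817 and 37435 bp from it, and its mean over all libraries was 0.37 windows. With all intervals of a -log10 q of 2 or more, the interaction of Ifi27l2b turned to -0.3. Over the alternatives, omissions of a library included, Zbtb4 kept its call in 2 and lost it in 18, Fgf12 in 5 and 16, Parg in 7 and 14, and Ucp2 in 17 and 4. Ifi27l2b kept its call in 7, lost it in 11 and changed direction in 1. For D542G no gene passed (897 at an unadjusted p under 0.05). Y541S vehicle libraries and 6 of the 9 WT giredestrant libraries share a run of library numbers, and with the run as a covariate limma called 42 genes for Y541S. This covariate is estimated from the WT giredestrant libraries alone, so the 42 calls have the limit given above.

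In libraries labelled Basal, giredestrant was compared with vehicle over the 3 genotypes. Sephs1, a selenophosphate synthetase homologue (chromosome 2, 4881564 to 4910557, GRCm38), had 2.89 ± 0.33 windows under giredestrant and 1.78 ± 1.39 under vehicle (SD, n = 9 each). Its log2 difference was 0.71 ± 0.09 SE (limma adjusted p = 6e-05). The difference came mostly from Y541S mice, where all 3 vehicle libraries had 0 windows and the giredestrant libraries 2.67 ± 0.58. In Y541S mice treatment coincides with the run of library numbers. Of the windows of Sephs1, 2 were closed in these vehicle libraries and open in the other 48, which include others of the same run. Ccdc28a had 2 ± 0 and 2.33 ± 0.50 windows (log2 difference -0.14 ± 0.02 SE, adjusted p = 0.00411). Cope, a subunit of the COPI vesicle coat, had 1 ± 0 and 1.33 ± 0.50 (log2 difference -0.19 ± 0.04 SE, adjusted p = 0.0339). For Cope and Ccdc28a the additional window was open in 3 libraries, those labelled Basal from D542G mice under vehicle. A window open in so few libraries is kept only when 2 or more of them share a labelled group. Cope also met the filter on genes through these libraries alone. The filters thus favoured this pattern, so the p-values of Cope and Ccdc28a do not support a difference. None of the 22 lists passed. With 25000 intervals per library the log2 difference of Sephs1 was -0.67 and that of Ccdc28a 0.18, neither past the threshold. Both genes also changed direction with all intervals of a -log10 q of 2 or more. Over the alternatives, omissions of a library included, Cope kept its call in 8 and lost it in 18.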

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

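The tests of the spread in this part were chosen after the results were seen. The effect of giredestrant on libraries labelled ML differed between Y541S and WT for 6 genes, by the interaction term of the limma model. The log2 interactions of those reported were -3.03 for Fgf12, 2.72 for Zbtb4, 1.86 for Ifi27l2b, -1.21 for Parg and 1.17 for Ucp2. Only 1 of 100 splits that exchange Y541S and WT libraries within a treatment, the real one, called as many genes. The highest of the others called 3. The windows had been kept by the labelled groups, which can favour the real split, and this comparison had the most calls of 16. Chance placement is therefore not excluded. The calls fell to 1 with the summit inside the window, 0 with all intervals of a -log10 q of 2 or more and 0 with a spread of each gene at least the trend. They were 5 each with 25000 intervals, the gene body extended by 20 kb and no filter on genes, and rose to 21 with the number of intervals and 42 with the run of library numbers as a covariate. Leaving out each library in turn gave 1 to 26 calls. The run of library numbers is uneven over the 4 groups and stays open, since its covariate is estimated from the WT giredestrant libraries alone. A different response of the Y541S receptor also stays open, and was not tested apart from the run.

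Genes with few windows can show the same count in every library of a group, so that their estimated spread is close to 0. This may produce calls from the difference of a single window. Of the 16 calls over 16 comparisons, 8 had no spread on either side, and no called gene had a mean above 2.63 windows. When no gene was given a spread below the trend of genes with its mean, 1 call was left, that of Sephs1 in libraries labelled Basal. The log2 differences are the same in that fit; the calls ended because the spread was larger. That fit can only raise a spread, so a gene whose spread is truly low would lose its call too. The loss of the other 15 calls therefore cannot decide whether their spread was estimated too low. In Y541S and WT libraries labelled ML, Parg had an SD of 0.58 windows under either treatment. Fgf12 and Zbtb4 had an SD of 0 in Y541S giredestrant libraries and 0.58 to 1.73 in the others. The interaction calls of these genes do not rest on identical counts in every group. A biological explanation for the 15 calls was not tested.

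Between 1 and 18 entries per library lay on chromosome Y, which the comparisons do not use. The highest was 18, against 3334 to 6424 entries on chromosome X.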

How the results depend on the processing

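The fits on genes with a mean of 4 or more windows and on a spread of each gene at least the trend were chosen after seeing the data; the other alternatives were fixed before. The comparison of N with ML, LP and Basal kept 0 called genes under every alternative that used all libraries, as did LP against ML. Many other counts moved beyond 1.5 times of the reported one under some alternative and kept within it under others, and the cause was not tested unless stated. Depth is unknown, so what it limits could not be measured.

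With 25000 intervals per library, limma called 1 gene for giredestrant in WT ML libraries, 15 in D542G and 13 in Y541S, and 15 in Basal libraries. It called 23 for Y541S against WT under vehicle, 7 for D542G, 2 for D542G under giredestrant, 1 for the D542G interaction and 2 for ML against Basal. Windows open on one side only numbered 0 for N against Basal and 1750 for giredestrant in D542G. The log2 difference turned to -0.67 for Sephs1 and to 0.18 for Ccdc28a. With all intervals of a -log10 q of 2 or more, the calls were 44 for giredestrant in WT ML libraries, 0 in D542G and 0 in Basal. They were 0 for N between mutants, 0 for D542G against WT under vehicle, 0 for the Y541S interaction and 5 for the D542G interaction. One-sided windows then numbered 5 for N against ML, 2 against LP, 6 against Basal and 4986 for giredestrant in WT, and the log2 value was -0.08 for Sephs1, 0.12 for Ccdc28a and -0.3 for Ifi27l2b.

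With the summit inside the window, the calls were 0 for N between mutants and 1 each for giredestrant in Basal, D542G against WT under vehicle, D542G under giredestrant and the Y541S interaction. One-sided windows numbered 0 for N against ML and 2 against Basal. With the gene body extended by 20 kb, the calls were 0 for N between mutants, 4 for giredestrant in WT, 1 in D542G and 0 in Basal. They were 7 for Y541S against WT under vehicle, 0 for D542G and 1 for the D542G interaction. With no filter on genes, which tests more genes, the calls were 2 for N between mutants, 12, 16 and 8 for giredestrant in WT, D542G and Y541S ML libraries, and 13 in Basal. They were 11 and 13 for Y541S and D542G against WT under vehicle, 5 and 5 under giredestrant, 1 for the D542G interaction and 3 for ML against Basal.

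As a covariate, the run of library numbers is estimated from the WT giredestrant libraries alone, whose replicates differ in basal windows between the runs. With this covariate, the calls were 3 for giredestrant in WT, 19 in Y541S, 1010 for Y541S against WT under vehicle, 1 each for Y541S and D542G under giredestrant, and 42 for the Y541S interaction. With the number of intervals as a covariate they were 324 for giredestrant in WT, 4 in Y541S, 275 for Y541S against WT under vehicle and 21 for the Y541S interaction. With the replicate number as a block they were 1 for giredestrant in WT, 1 for D542G against WT under giredestrant and 1 for the Y541S interaction. Not every pair of the same genotype, treatment and number was alike, so the libraries were taken as unpaired. Of 54 such pairs, 32 had a correlation of deviations over 0.1, with a median of 0.296 and a lowest value of -0.816. Of 354 pairs of the same number with another genotype or treatment, 130 did, with a median of -0.0254. The higher median is a hint from the data, not the design. Among genes with a mean of 4 or more windows, which leaves out each called gene, the calls were 0 for N between mutants, giredestrant in D542G and in Basal, D542G against WT under vehicle and the Y541S interaction. With a spread of each gene at least the trend they were 0 in the same comparisons, except 1 in Basal, because the spread was larger. With an estimated correlation, 0 of the 7 calls of gene lists passed.

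Leaving out each library in turn gave 0 to 1 calls for N against ML, LP and Basal (1 without N D542G replicate 1 in each, and for LP also without LP D542G replicate 3). It gave 0 to 5 for N between mutants (5 without N D542G replicate 1). For giredestrant in ML libraries it gave 0 to 28 in WT (28 without vehicle replicate 3), 3 to 23 in D542G (23 without vehicle replicate 3) and 0 to 64 in Y541S (64 without vehicle replicate 2), and in Basal 2 to 6 (6 without Y541S vehicle replicate 1). Against WT under vehicle it gave 0 to 190 for Y541S (190 without Y541S replicate 2) and 1 to 27 for D542G (27 without WT replicate 3). Under giredestrant it gave 0 to 6 and 0 to 9 (both highest without WT replicate 3). The interactions gave 1 to 26 for Y541S (26 without Y541S vehicle replicate 2) and 0 to 6 for D542G (6 without WT vehicle replicate 3). ML against Basal gave 0 to 3 and LP against ML 0. One-sided windows ranged from 1 to 6 for N against ML, 0 to 3 against LP, 1 to 5 against Basal and were 0 for ML against Basal. For giredestrant they ranged from 1422 to 4895 in WT, 3504 to 9489 in D542G and 714 to 2239 in Y541S, where fewer libraries make the condition easier to meet. Of the tests of the named called genes under these omissions, 97 kept the call and 59 lost it, with no change of direction.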

Other observations

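The tests in this part were chosen after the results were seen. On windows kept by the labelled groups, but with no other use of the labels, the main axis of variation over the 51 libraries and 13993 genes held 40.2% of the variance and set the basal list against the pan-luminal list. The basal list had a median loading of 0.42 and the Wnt list, of a pathway active in basal mammary cells, 0.32, both at or above all of 10000 random lists matched on the number of windows. The pan-luminal list had a median of -0.19, at percentile 0.05. The other luminal lists did not lie at this end as clearly, with medians of -0.05 for mature luminal (percentile 10.9), 0 for luminal progenitor (39.7) and 0.01 for milk and alveolar (51.6). Krt5, from 0 to 7 windows, loaded at 1.05 and Acta2, smooth muscle actin, at 0.71. Stac, Reln and Ntrk3 loaded highest, at 1.68, 1.41 and 1.35. At the other end stood Adra1a, at -1.46, the mucin gene Muc4, at -1.18, and Prlr, at -1.18. Esr1 had a loading of -0.02, with 6 to 13 windows in every library.

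The next axis held 12.4% of the variance. The luminal progenitor list lay at one end, with a median loading of 0.15 and percentile 99.98, and the mature luminal list at the other, with -0.13 and percentile 0.03. The basal list (-0.07, percentile 0.21) and the fibroblast list (-0.11, percentile 0.22) lay at this end too, so it is not specific to mature luminal genes. Wfdc18 (0.57), Kit (0.38) and Elf5 (0.38) lay on the progenitor side, with Mgam (0.92) and Clnk (0.91) at its end. Cdh13 (-1.01), Kif21a (-0.80) and Greb1 (-0.30) lay on the other side. The percentiles describe these libraries and are no test across samples.

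Libraries of a labelled group were on average no more alike than others. The mean Jaccard index was 0.598 within labelled groups of 3 and 0.603 between them (permutation test, p = 0.784). It was 0.618 within and 0.596 between labelled genotypes (permutation test, p = 0.0181, adjusted p = 0.0543), and 0.608 and 0.594 for the runs of library numbers (p = 0.0427, adjusted p = 0.0854), so a tie to these is not excluded. By the same index, the nearest library to each of the 51 was of the same labelled population in 11 cases. A mixture of basal and luminal cells in the sorts could place libraries midway, and 2 of 51 lay in the middle part when the main axis was cut into 3 equal lengths. Open or closed calls of a mixture need not fall midway, so this does not exclude one. In D542G mice under giredestrant, libraries labelled Basal (replicate 2), N (2) and ML (3) each had 7 windows at Krt14. At Prlr they had 7, 4 and 5. A change of cell identity by giredestrant or by a mutation would leave WT vehicle groups uniform, if their genotype and treatment labels hold. Yet their libraries labelled ML and Basal ranged over 3.85 and 3.65 windows per basal gene. A candidate explanation is that the labels are displaced from the files: libraries that follow one another in the order of deposit, taken 3 at a time, had a mean index of 0.803. Each of these 17 runs lies within 1 labelled genotype and treatment, so the arrangements were drawn within these, and the highest of 100000 had 0.733 (permutation test, p = 1e-05, the smallest it can give). Shared animals or handling in a run may add to this and were not tested. In D542G mice under vehicle, libraries labelled Basal had 3.10 to 3.60 windows per basal gene and those labelled ML 3.60 to 4.05 (n = 3 each). Displacement within a genotype and treatment does not account for a condition without a basal profile. Over all conditions, 18 libraries had 6 or more windows per basal gene, and 18 were labelled Basal. This bound was set after the values were seen. Displacement across conditions was not tested and stays open, so the genotype and treatment labels may be in doubt too. The order of deposit gives no library a condition, and a person with the original sample sheet would have to settle the labels, so no library was moved here.

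There were 1711 windows closed in exactly 3 libraries. The 17 runs of 3 in order of deposit held 139, most of them in 3 runs with 59, 51 and 14, and a trio that is no run held 47, so these windows do not speak for all runs. The 17 labelled groups held 2, against 1.40 expected with an equal share for every trio. The shares of trios are unequal here and the 2 windows are neighbours, so this cannot decide whether chance gives as many. Both windows lie at the lower-coordinate end of Sephs1, on chromosome 2 from 4881559 to 4882059 and from 4882192 to 4882692, and are open in the other 48 libraries. The 3 libraries where they are closed are labelled Basal, from Y541S mice under vehicle. Why these windows are closed there was not tested.

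For the comparisons where the 3-against-3 design gives 10 splits, no share under 0.05 can be reached. The real and the highest other counts of genes were 1 and 0 for N between mutants and 4 and 2 for giredestrant in D542G ML libraries. They were 0 and 9 for giredestrant in WT, 0 and 5 in Y541S, 0 and 26 for Y541S against WT under vehicle, 2 and 2 for D542G, and 0 and 2 for each mutant under giredestrant. The number of splits with as many genes was 1, 1, 10, 10, 10, 3, 10 and 10 of 10. With 100 splits, 7 called at least the 3 genes of the Basal comparison (highest other 7), so chance is not excluded there. With 0 genes called, all 100 splits gave as many for N against ML, LP and Basal (highest other 3, 2 and 2), for the D542G interaction (1), ML against Basal (22) and LP against ML (609). For LP against ML the median of the splits other than the real one was 0, and the count of 609 is that of a single split. It shows that these libraries can be divided so that they differ more than by the labels.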
